A study of Homo sapiens with 5 samples.

How the data were processed

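RNA of 3 human renal cell carcinoma lines was hybridised to 5 Affymetrix arrays: SN12C (2 arrays), LM1 (1) and LM2 (2). The authors deposited 1 log2 signal per probe set and array. Per the submitters' processing notes, RMA and Partek were used, with no versions given in the sources used here. RMA corrects background, quantile normalizes and summarises probes on the log2 scale, so differences between arrays in total signal are removed before deposit. No value was transformed again. Array medians lay between 6.51 and 6.57. Many values are identical between arrays: 714 tested genes had equal deposited values in both SN12C arrays, 2131 in both LM2 arrays and 169 in both pairs. Such ties shrink the estimated spread of those genes. How they arose is not given in the sources used here.

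Of 54675 probe sets, 62 controls were left out of the tests. A platform table named 42898 probe sets, 41097 with 1 gene and 1801 with several. The 11777 it did not list were not named here, and none with several genes was used. Of the probe sets with 1 gene, 41043 matched a gene table of assembly GRCh38.p14, which was used only for names, chromosomes and the order of genes, and 0 symbols changed through it. For each of 19775 genes the probe set with the highest mean was kept, and a gene was tested where at least 2 arrays reached the 40th percentile of all values, 6.03. Of the 15030 probe sets tested, 1058 end in _x_at and 4071 in _s_at, types that can bind several transcripts.

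Samples were grouped by the labels. The model had 1 mean per line over all 5 arrays, fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. It has 2 residual degrees of freedom and 1.3 prior ones. An exact permutation test of 2 against 2 arrays cannot go below p = 0.333, two-sided. The comparisons were LM2 with SN12C, LM1 with SN12C, LM2 with LM1, and LM1 with the midpoint of the others. Figures were drawn with matplotlib 3.10.9.

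Gene lists (34, holding 714 genes, 577 of them tested) were written from general knowledge. They covered chemokines, NF-kappaB, interferon, TGF-beta and stress responses, cell cycle, matrix, adhesion, metabolism, identity, and 5 sets of markers of other cell types. Lists, chromosomes and runs of 100 neighbouring genes were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Members were also adjusted over the list alone, without correction over the lists or the comparisons. The rule for named genes was the largest differences past the threshold with arrays that do not overlap, or, where none passed, the 5 largest on each side, plus up to 4 members of each list, members passing over the list alone being added after their values were seen. XIST and Y-linked genes were left out. List genes that the platform table did not name were not used here.

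Groups, tests, lists, the naming rule and most alternatives were fixed before the data were examined. Alternatives covered the filter, the probe set rule, quantile normalization, centring, eBayes options, the arrays in the fit, each replicate left out and a replicate block. Leaving out genes with tied values, and some settings for lists and the overlap, were added after seeing the data.

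The gene test was tested on simulated data for LM2 against SN12C with 200 of 15030 genes changed. With each gene's spread drawn from the fitted prior, 1.5% of genes changed by 1 log2 unit, 56.7% by 2 and 86.4% by 4 were recovered, with 12 false calls. With the fitted spread per gene, 46.3%, 88.1% and 100% were recovered, with 3 false calls. The list test called the 1 list moved and 0 of the others. Simulated genes varied independently, so this does not test list calls where members vary together. All simulated arrays of a gene had the same spread, and no values were tied. The measured SN12C arrays stood a median of 0.28 log2 units apart and the LM2 arrays 0.07, and many values were tied. The recovered shares may therefore not hold for the measured arrays. For the shared SN12C arrays, 100 simulations of unchanged groups were run, and 100 with the LM2 differences as measured and no LM1 effect. Differences that share no array were added after seeing the data.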

Results

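Gene expression was measured on 5 Affymetrix expression arrays in 3 related human renal cell carcinoma lines. SN12C, the parental line, which the labels call non-metastatic, had 2 biological replicates. LM1, the line of lung-metastatic generation 1, had 1 array, and LM2, of lung-metastatic generation 2, had 2 biological replicates. According to the series description, the lines were profiled to find expression differences that go with rising metastatic activity. Each array held 54675 probe sets, and 15030 genes were tested, each through 1 probe set. The median signal of an array lay between 6.51 and 6.57 log2 units. The number of arrays limits the precision, and LM1 has no replicate of its own. Whether the replicates were separate cultures beyond the label "biological" is not stated, so p-values measure the spread between these arrays.

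The arrays differed in quality and in resemblance. Beta-actin signal at the 3' end exceeded that at the 5' end by 3.43 log2 units on the LM1 array and by 0.07 to 0.47 on the other 4. For GAPDH the difference was 2.09 on the LM1 array and between -0.07 and 0.14 on the others. The middle and 5' probe sets of 18S ribosomal RNA read 8.68 and 8.80 on SN12C replicate 1 and 8.49 and 8.61 on LM1, against 7.43 to 7.83 on the other arrays. The 3' probe set read 8.49 on SN12C replicate 1 and 9.71 on LM1, against 7.98 to 8.22 on the others. The SD of all values was 2.11 on SN12C replicate 1 and 2.22 to 2.25 on the other arrays. The LM2 replicates correlated across genes at r = 0.997, with 8 genes at least 1 log2 unit apart. The SN12C replicates correlated at r = 0.971, with 634 such genes. SN12C replicate 2 correlated with the LM2 arrays at 0.980 and 0.983, above its correlation with SN12C replicate 1. These correlations are across genes, which are not independent replicates.

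**Figure D1:**
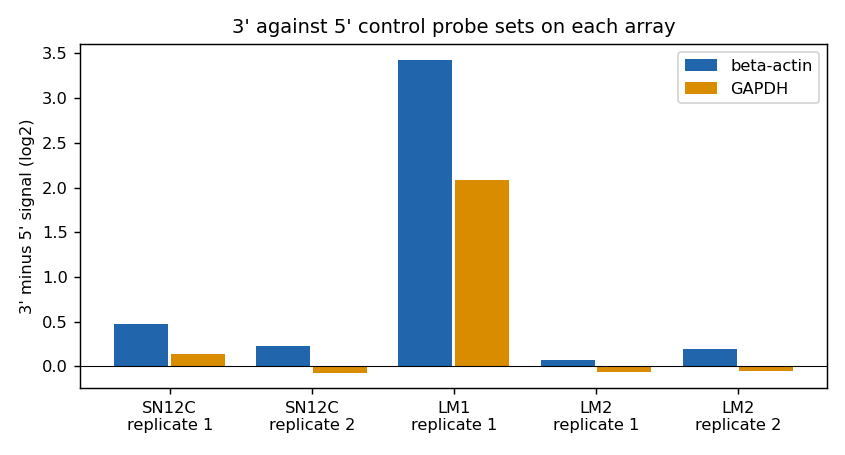
Difference between 3' and 5' control probe sets (log2 signal, y axis) on each of the 5 arrays (x axis) for beta-actin and GAPDH; each bar is 1 array. The LM1 bars stand at 3.43 and 2.09, and those of the other arrays lie between -0.07 and 0.47.

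The first comparison, LM2 against SN12C, sets the most metastatic generation against its parent. The neutrophil-attracting chemokines fell as a group in LM2: the 7 measured members had a median difference of -3.44 log2 units, and all 7 were lower (limma camera, adjusted p = 0.00019). This call was lost in camera at adjusted p = 0.772 with an estimated correlation, and fry gave an adjusted p of 0.0794. Without probe sets ending in _x_at or _s_at too few of its members were left for a test. CXCL5 fell from 11.35 ± 0.19 to 7.38 ± 0.19 (SD, n = 2 each). In limma its adjusted p was 0.000563, adjusted over the list alone. CXCL2 fell by 4.71 (limma adjusted p = 0.0416, adjusted over the list alone). CXCL8, the neutrophil chemoattractant interleukin 8, was 11.27 ± 2.86 in SN12C and 5.82 ± 0.55 in LM2, a difference of -5.46 that missed the threshold (limma, adjusted p = 0.0645 over the list). MIF, macrophage migration inhibitory factor, was 13.33 ± 0.22 in SN12C and 7.20 ± 1.09 in LM2. COL11A1, a fibrillar collagen chain, was 5.60 ± 0.26 in SN12C and 9.76 ± 0.03 in LM2.

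Over all genes, none of the 15030 passed an adjusted p of 0.05 in limma (lowest adjusted p = 0.225), so by the rule for naming genes the 5 largest differences on each side are given, none of which passed. They were COL11A1 at 4.16 ± 0.16 (SE), FAM133A at 3.89 ± 0.54, CRIP1 at 3.84 ± 0.77, S100A4 at 3.70 ± 0.33 and TMEM200C at 3.64 ± 0.49 log2 units higher in LM2. On the other side stood MIF at -6.12 ± 0.61, CXCL8 at -5.46 ± 1.61, CXCL2 at -4.71 ± 0.93, CXCL5 at -3.97 ± 0.17 and CXCL1 at -3.44 ± 0.91. For all 10 genes the arrays of SN12C and LM2 did not overlap. Both SN12C values of COL11A1 and TMEM200C, both LM2 values of CXCL1 and the LM2 mean of CXCL8 lay below the filter value of 6.03, near background, so the sizes and ranks of these differences are uncertain. CRIP1 encodes a small LIM-domain protein and S100A4 a calcium-binding protein linked to cell motility. Further probe sets of COL11A1 gave 3.04 and 1.29, of FAM133A 3.06 and of CXCL8 -3.39, while a second probe set of TMEM200C gave 0.03. For CXCL2 the other probe sets gave -0.36 and -0.09, and for CXCL5 -2.80 and -0.40, each dimmer than the one used. CRIP1, S100A4, MIF and CXCL1 were each read by a single probe set. The probe sets of CXCL8, CXCL2 and CXCL5 are of a type that can also bind related transcripts, so values of these chemokines are uncertain as to member. Those of MIF and S100A4 end in _s_at, a type that can bind several transcripts too. At an unadjusted p under 0.05 there were 1739 genes, where chance gives 751.5. Of the 449 genes at least 1 log2 unit apart, 349 also had such a p, 187 higher and 162 lower in LM2. A fit without an SN12C array takes its spread from the LM2 pair alone, whose arrays stood a median of 0.07 log2 units apart, against 0.28 for the SN12C pair, so p-values from such a fit say little about SN12C. That fit gave 790 such genes higher and 216 lower without replicate 2, with 3835 called, and 98 and 139 without replicate 1, with 0 called. A fit without an LM2 array takes its spread from the SN12C pair, and gave 85 and 85 without LM2 replicate 1 and 90 and 104 without LM2 replicate 2. Groups did not overlap for 39.4% of genes, against 33.3% by chance.

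**Figure D2:**
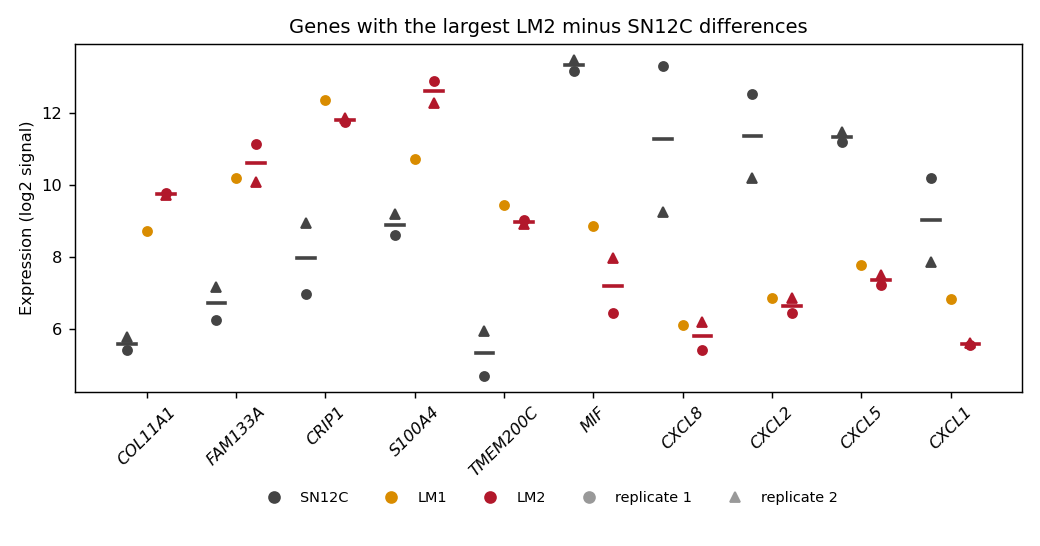
Expression (log2 signal, y axis) of the 10 genes with the largest LM2 minus SN12C differences (x axis); points are single arrays, coloured by line with the shape giving the replicate, and short lines are means of 2 arrays. CXCL8 stood at 13.30 and 9.25 in the SN12C arrays, and CXCL5 at 11.21 and 11.48.

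Beyond the chemokines, lists of inflammatory and stress genes were lower and lists of replication and mitosis genes higher in LM2 by camera. Of 34 gene lists, 10 passed camera with a preset correlation of 0.01, 8 lower and 2 higher. With a correlation estimated from these arrays 0 lists passed (lowest adjusted p = 0.772 with an estimated correlation). The fry test, which asks whether a list moves one way on balance, passed 3 other lists, integrins and adhesion receptors, the unfolded protein response and fibroblast markers (adjusted p = 0.045 each).

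The NF-kappaB inflammatory list, which shares chemokines with the list above, fell with a median of -0.86 (camera adjusted p = 4.4e-08; adjusted p = 0.772 with an estimated correlation), and 22 of 23 members were lower. IL6 had a difference of -2.92 ± 0.48 log2 units and CXCL3 had a difference of -3.29 ± 1.25; 0 members passed adjusted over the list alone. The integrated stress response list fell with a median of -0.42 (camera adjusted p = 0.000278; adjusted p = 0.874 with an estimated correlation), 23 of 25 members being lower. Its leading members were DDIT4 at -1.76, ATF3 at -1.71, DDIT3 at -1.52 and CEBPB at -1.41, and 0 of 25 passed alone. Immediate early genes fell with a median of -0.18 (camera adjusted p = 0.00489; adjusted p = 0.772 with an estimated correlation). ATF3 (-1.71) and DUSP1 (-0.79) fell among 18, adjusted over the list alone, while IER3 (-1.52) and NR4A2 (-1.11) did not pass. The list stood at -0.43 against SN12C replicate 1 and -0.04 against replicate 2.

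In the DNA replication list, which rose with a median of 0.75 (camera adjusted p = 0.00626; adjusted p = 0.874 with an estimated correlation), 24 of 27 members were higher, and 0 passed alone. CCNE2, a G1/S cyclin, stood at 6.91 and 9.78 in the SN12C arrays and at 9.94 and 9.92 in LM2; CDC6 was at 8.70 and 10.68 against 10.75 and 10.86. The differences of MCM4 and MCM10 were 1.00 and 0.93. The mitosis list rose with a median of 0.32 (camera adjusted p = 0.0114; adjusted p = 0.874 with an estimated correlation), 21 of 25 members being higher. Its largest differences were mixed, with UBE2C at -1.06, PLK1 at 0.81, BIRC5 at 0.60 and KIF23 at 0.49, and 0 passed alone. These groups also differed between the SN12C replicates. Replicate 1 exceeded replicate 2 by a median of 2.33 for the chemokines, 0.76 for the NF-kappaB list and 0.72 for the integrated stress response, and stood -0.97 from it for DNA replication. Against SN12C replicate 2 alone, LM2 had medians of -2.27 for the chemokines, -0.69 for NF-kappaB, -0.08 for the integrated stress response, 0.13 for DNA replication and 0.16 for mitosis, which stood at 0.48 against replicate 1. Without SN12C replicate 1 the camera calls of the integrated stress response (adjusted p = 0.951), DNA replication (0.487), mitosis (0.449) and immediate early genes (0.149) were lost, with the spread of the LM2 pair alone. The mitosis call was also lost with the 60th percentile filter (0.0507). Without _x_at and _s_at probe sets the calls of mitosis (0.13), DNA replication and immediate early genes (0.067 each) were lost. Without SN12C replicate 1, 6 lists passed, and without replicate 2, 6 passed.

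**Figure D3:**
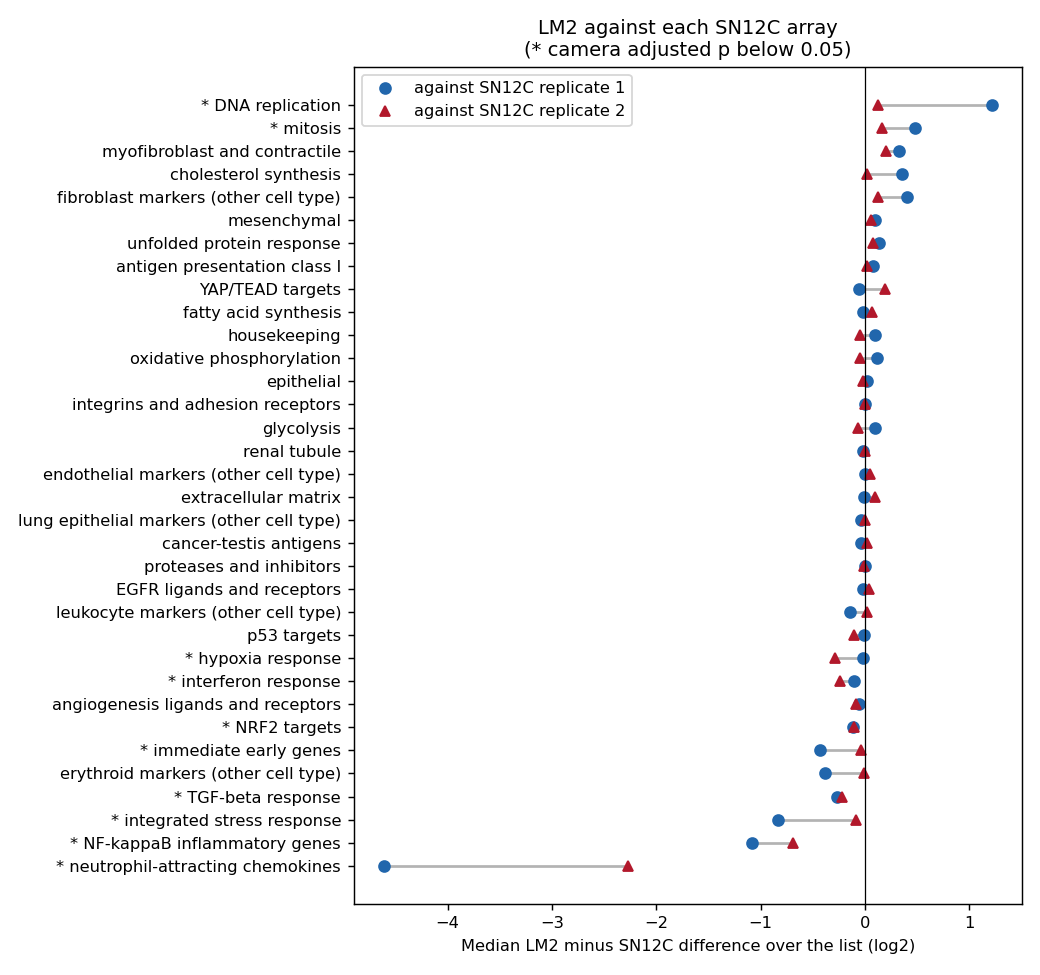
Median LM2 minus SN12C difference (log2, x axis) over each of 34 gene lists (y axis), computed against SN12C replicate 1 (circles) and replicate 2 (triangles); an asterisk marks lists with a camera adjusted p below 0.05. The chemokine list stood at -4.61 and -2.27, and DNA replication at 1.22 and 0.13.

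A fall was called in 4 further lists, each with an adjusted p of at least 0.772 with an estimated correlation. Their medians against SN12C replicate 1 and replicate 2 were -0.02 and -0.29 for hypoxia, -0.10 and -0.24 for interferon, -0.27 and -0.22 for TGF-beta and -0.11 and -0.10 for NRF2. The TGF-beta response list fell with a median of -0.27 (camera adjusted p = 0.016), with TGFBI at -2.46, ID3 at -1.33, ID2 at -1.03 and TSC22D1 at 1.02, and 0 of 24 passed alone. The interferon response list fell with a median of -0.11 (camera adjusted p = 0.00626), with BST2 at -1.41, IFI6 at -0.97, MX2 at 0.84 and ISG20 at -0.69, and 0 of 26 passed alone. The hypoxia list fell with a median of -0.09 (camera adjusted p = 0.0188). PDK1 (-1.10) and PFKFB3 (-0.66), both regulators of glucose use, fell among 28, adjusted over the list alone, while LOX (2.15), HK2 (-0.79) and SLC2A3 (-0.75) did not pass within this list. NRF2 targets fell with a median of -0.16 (camera adjusted p = 0.0201), led by HMOX1 at -2.42, SLC7A11 at -0.89, ME1 at -0.76 and TALDO1 at 0.44, and 0 of 15 passed alone. With the spread of the LM2 pair alone, all 4 calls were lost without SN12C replicate 2 (camera adjusted p = 0.309 for TGF-beta, 0.342 for interferon, 0.65 for hypoxia and 0.0728 for NRF2), and that of NRF2 also without replicate 1 (0.101). That of TGF-beta was also lost without LM2 replicate 2 (0.0506) and that of hypoxia without LM2 replicate 1 (0.0588), and both without _x_at and _s_at probe sets (0.456 and 0.556). The hypoxia call was also lost with camera on ranks (0.0568).

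Matrix and cytoskeletal genes differed in both directions, though 0 passed over all genes. The values adjusted over the list alone are not corrected over the lists or the comparisons. Adjusted over the list alone, 10 of 24 extracellular matrix genes passed: LOX (2.15), LOXL1 (1.87), COL1A2 (from 6.79 ± 0.52 to 8.29 ± 0.01), COL6A1 (1.11), COL6A2 (1.07) and LOXL2 (0.68) rose, and COL5A2 (-3.33), TNC (-2.94), COL8A1 (-2.43) and THBS1 (-1.27) fell. The list as a whole had a median of -0.01 and a mean of 0.13 (camera adjusted p = 0.803). LOX, LOXL1 and LOXL2 encode enzymes that cross-link collagen. In the myofibroblast and contractile list CALD1 (3.54), TGFB1I1 (1.31) and MYLK (1.22) rose and CNN1 (-1.10) and PALLD (-1.04) fell among 21, adjusted over the list alone, with a list median of 0.31 (camera adjusted p = 0.16). Other probe sets of CALD1 ranged from -0.42 to 2.98. For the matrix genes above, and for KRT19 below, other probe sets were not compared gene by gene. Among 22 mesenchymal genes S100A4 (3.70), WNT5B (1.14) and CDH2 (0.57) rose, adjusted over the list alone (list median 0.12, camera adjusted p = 0.274). Among 20 epithelial genes the keratin KRT19 rose by 2.52 and 0 fell, adjusted over the list alone (median 0.01, camera adjusted p = 0.82).

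Single members of further lists passed adjusted over the list alone. L1CAM, a cell adhesion molecule, rose by 2.40 among 21 integrins and adhesion receptors (median 0.00, camera adjusted p = 0.82). FGF1 (1.63), EFNB2 (1.13) and NRP1 (0.81) rose and PDGFC (-1.32) and THBS1 (-1.27) fell among 23 angiogenesis genes (median -0.12, camera adjusted p = 0.335). PHLDA1, itself neither a ligand nor a receptor, fell by 1.66 among 16 genes of the list named EGFR ligands and receptors (median -0.04, camera adjusted p = 0.803). MDM2 fell by 0.95 among 19 p53 targets (median -0.07, camera adjusted p = 0.172). SEL1L (0.60) and CRELD2 (0.49) rose among 17 unfolded protein response genes (median 0.09, camera adjusted p = 0.172). TGFB2 rose by 0.72 among 17 YAP/TEAD targets (median 0.07, camera adjusted p = 0.803), and GUSB by 0.63 among 14 housekeeping genes (median 0.04, camera adjusted p = 0.902).

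In the lists of metabolism and identity 0 members passed adjusted over the list alone. The medians were 0.00 for glycolysis (camera adjusted p = 0.522), 0.02 for oxidative phosphorylation (0.902), 0.22 for cholesterol synthesis (0.82) and 0.06 for fatty acid synthesis (0.938). For renal tubule genes the median was 0.00 (0.82), for class I antigen presentation 0.07 (0.876), for proteases and their inhibitors -0.02 (0.439) and for cancer-testis antigens -0.02 (0.902), whose mean was 0.15. CD24 in the renal tubule list differed between the SN12C arrays, at 7.68 and 11.10, and was 6.67 and 7.31 in LM2. Markers of other cell types did not pass camera. The medians were -0.06 for leukocyte markers (adjusted p = 0.522), -0.01 for endothelial (0.82), -0.02 for lung epithelial (0.82), 0.19 for fibroblast (0.323) and -0.20 for erythroid markers (0.369). Of these markers, KDR, the VEGF receptor, fell by 1.42 (limma adjusted p = 0.0121, adjusted over the list alone). The fibroblast list shares COL3A1, COL1A2, THY1 and FBLN1 with lists above.

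Expression also differed by chromosome. In LM2, genes of chromosomes 2 (median -0.11), 4 (-0.14) and 1 (-0.04) were lower and those of chromosomes 21 (0.35), 14 (0.23), 16 (0.15), X (0.13) and 7 (0.10) higher, against a median of 0.03 over all genes. These 8 of 23 chromosomes passed camera (adjusted p from 4.1e-11 for chromosome 4 to 0.0253 for chromosome 7). With an estimated correlation 0 passed (lowest adjusted p = 0.8 with an estimated correlation), and without SN12C replicate 2, with the spread of the LM2 pair alone, 3 passed. On chromosome 4, 70.4% of 514 genes were lower in LM2, and on chromosome 2, 69.9% of 951, against 44% of all genes. Of 152 runs of 100 neighbouring measured genes, 48 passed, among them 10 of 10 on chromosome 2, 5 of 5 on chromosome 4, 5 of 5 on chromosome 14 and 2 of 2 on chromosome 21. On chromosome 1 the first 6 of 15 runs passed, with medians from -0.19 to -0.11, and the others did not. Against SN12C replicate 1 and replicate 2 alone, where all genes had medians of 0.06 and 0.00, chromosome 4 had medians of -0.11 and -0.19, chromosome 2 of -0.05 and -0.17 and chromosome 1 of -0.01 and -0.03. Those of chromosome 21 were 0.42 and 0.24, of 14 0.35 and 0.12, of 16 0.22 and 0.09, of X 0.20 and 0.07 and of 7 0.14 and 0.05.

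**Figure D4:**
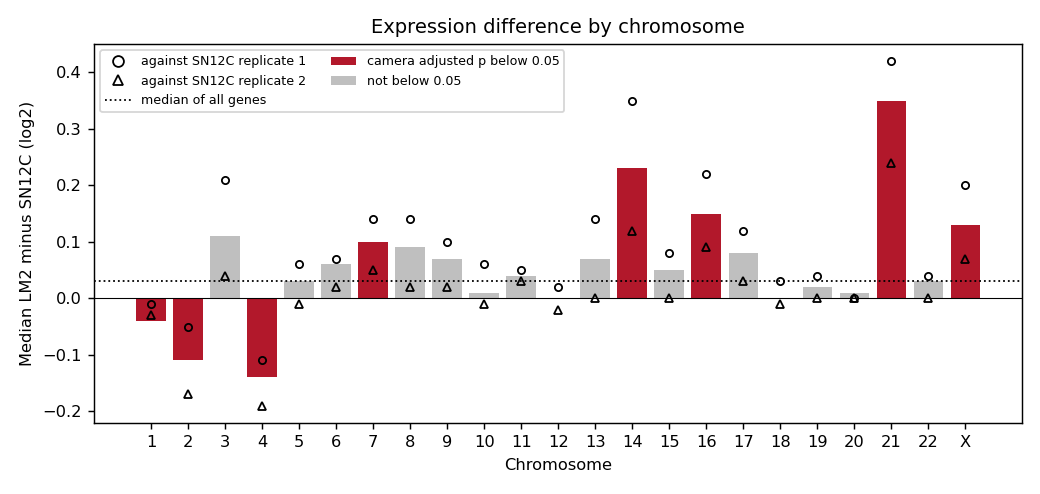
Median LM2 minus SN12C difference (log2, y axis) of the genes on each chromosome (x axis); bars use both SN12C arrays and are red where the camera adjusted p was below 0.05, open circles and triangles use SN12C replicate 1 or 2 alone, and the dotted line is the median of all genes. Chromosomes 2 and 4 stood at -0.11 and -0.14, and chromosome 21 at 0.35.

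The second comparison, LM1 against SN12C, asks what already differed in generation 1. The chemokines fell in LM1 too, with a median of -3.44 and all 7 members lower (camera adjusted p = 0.000455; adjusted p = 0.864 with an estimated correlation), and CXCL5 fell by 3.56 (limma adjusted p = 0.00156, adjusted over the list alone). The NF-kappaB list fell with a median of -0.71 (camera adjusted p = 1.6e-05), the integrated stress response with -0.42 (0.0131) and immediate early genes with -0.14 (0.0476), each with an adjusted p = 0.864 with an estimated correlation. Without SN12C replicate 1, with the spread of the LM2 pair alone, the calls of the integrated stress response (0.891) and immediate early genes (0.305) were lost, and without _x_at and _s_at probe sets too (0.188 and 0.681). The immediate early call was lost in 7 of 16 alternatives, among them no filter (0.116), the 40th percentile filter in 1 array (0.0542) and camera on ranks (0.158). Without SN12C replicate 1 the LM1 medians were -1.59 for the chemokines, -0.23 for NF-kappaB, 0.00 for the integrated stress response and -0.01 for immediate early genes. Without the filter the chemokine median was -2.18, and without _x_at and _s_at probe sets that of NF-kappaB was -0.37. CRIP1, TMEM200C, CALD1, PPP2R2B and FAM133A were 4.39, 4.12, 3.86, 3.48 and 3.47 log2 units higher in LM1. CXCL8, CXCL2, MIF, CXCL5 and the coagulation inhibitor TFPI had differences of -5.15, -4.51, -4.46, -3.56 and -3.49. Other probe sets did not all follow. The second of TMEM200C gave 4.91 in LM1 against 5.01 and 5.06 in SN12C, and that of PPP2R2B 5.07 against 5.42 and 5.21. Of CALD1, 1 gave 3.64 against 3.90 and 4.43, and another 7.55 against 7.68 and 7.38. The second probe set of FAM133A was higher in LM1, at 8.23 against 5.78 and 5.99. The SN12C means of TMEM200C (5.33) and CALD1 (5.67) lay below the filter value.

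With 1 LM1 array the spread in the main fit comes from SN12C and LM2, and LM1 is assumed to vary like them. The limma test called 0 genes (lowest adjusted p = 0.0964), with 3326 at an unadjusted p under 0.05 and 947 of these at least 1 log2 unit apart, 725 higher and 222 lower. That balance was 417 to 343 with the mean of all probe sets, 405 to 137 with only the SN12C and LM1 arrays, and 411 to 132 and 413 to 133 without LM2 replicate 1 or 2. With the spread of the LM2 pair alone it was 529 to 344 without SN12C replicate 1, with 2032 genes called, and 1668 to 220 without replicate 2, with 4862 called. These calls set 1 array against 1 array. The fry test passed 0 lists. Chromosomes 2, 4, 14 and 21 passed camera, with medians of -0.02, -0.03, 0.29 and 0.39 against 0.09 over all genes; each had an adjusted p = 0.902 with an estimated correlation. Adjusted over the list alone, CALD1 (3.86), L1CAM (3.15), KRT19 (2.78), COL6A1 (1.68), WNT5B (1.76) and CDH2 (1.49) were higher on the LM1 array than in SN12C. COL5A2 (-2.49), COL8A1 (-1.84), PHLDA1 (-2.11) and KDR (-1.17) were lower. These are a part of the members that passed. Among immediate early genes 7 passed, 3 higher and 4 lower, so the fall that camera called for that list was not shared by all its members. In the unfolded protein response 6 passed (5 higher), in the EGFR list 5 (2 higher), in the TGF-beta response 4 (3 higher) and among YAP/TEAD targets 3 (1 higher). All of these lie beside the raised 3' to 5' control difference of the LM1 array, 3.43 for beta-actin. Across 7195 genes with several probe sets, LM1 minus SN12C correlated between the 2 brightest at r = 0.202, against 0.671 for LM2 minus SN12C. The difference of the single arrays SN12C replicate 1 and replicate 2 gave r = 0.455. The LM1 differences may therefore depend on the probe set used.

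Differences in LM1 and LM2 ran together. Of the 349 genes at least 1 log2 unit apart with an unadjusted p under 0.05 in LM2 against SN12C, 335 (96%) differed in the same direction in LM1, and the median LM1 difference was 83.7% of that in LM2. These genes were chosen on the SN12C arrays that LM1 is also set against. Arrays simulated with no LM1 effect, where the same rule chose a mean of 611.4 genes, gave 62.3% and 6.9%. Those simulations took the measured LM2 differences, which already hold noise, as true. Their chosen genes are therefore not a like set to the 349, and the gap does not measure an LM1 effect. Across genes the differences correlated at r = 0.638 (Spearman's rho 0.595). Unchanged groups set against shared simulated SN12C arrays gave a mean r of 0.409. The covariance was 0.144 against 0.0214 simulated, a difference of 0.122. The same sign was seen for 73.4% of genes against 63.4% simulated. The simulations of unchanged groups gave every array of a gene the same spread. The measured SN12C pair differed more than the LM2 pair (SD of differences 0.458 against 0.145 log2 units). The simulated values may therefore understate what the shared SN12C arrays add, and the excess over them does not measure an LM1 effect. The number of genes called in both comparisons was 0, as 0 were called in either, and the expected number for independent lists was 0. The SN12C arrays were too few to split into sets of 2, so part of any excess may come from the shared arrays. In differences against single SN12C arrays that share no array, chosen after the result was seen, r was 0.287 (LM2 minus SN12C replicate 1 with LM1 minus replicate 2) and 0.415 (the reverse). The covariances were 0.0839 and 0.0984. Of the 1130 and 332 genes at least 1 log2 unit apart in LM2 there, 73.9% and 86.4% differed in the same direction in LM1, and the median LM1 difference was 33.7% and 65.1% of that in LM2.

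The third comparison, LM2 against LM1, asks what separated the generations. EIF5A, a translation factor, was 3.52 ± 0.12 (SE) log2 units higher in LM2, GTF2I 3.43, LMBR1 3.09, ZNF675 3.08 and RAP2B 3.01. The SE comes from the SN12C and LM2 pairs and holds no spread of LM1. SOD2, a mitochondrial superoxide dismutase, had a difference of -2.10, ZNF395 -1.88, COXFA4L3 -1.84, the insulin receptor INSR -1.83 and TBC1D24 -1.78. None passed in limma, which called 0 genes (lowest adjusted p = 0.178), with 2555 at an unadjusted p under 0.05. Fits that take their spread from the LM2 pair alone called 1297 genes with only the LM1 and LM2 arrays, and 1425 and 1436 without SN12C replicate 1 or 2. For each named gene but COXFA4L3 the single LM1 array lay outside the range of the SN12C and LM2 arrays. EIF5A read 13.76 and 13.83 in SN12C, 10.41 in LM1, and 14.02 and 13.84 in LM2. These differences are thus departures of that array from both other lines, while COXFA4L3 in LM1 lay between SN12C and LM2. The LM1 values of ZNF675 (3.84) and GTF2I (5.97) lay below the filter value. Other probe sets often differed: for EIF5A the LM1 array stood -3.45 from the midpoint of SN12C and LM2 on the probe set used and -0.94 and -0.49 on others. LMBR1 stood -2.40 on the probe set used and between -0.08 and 0.40 on others, and RAP2B -2.78 against 1.40, 0.38 and 0.00. On the lower side INSR stood 1.80 on the probe set used and between -0.03 and 0.22 on others, and TBC1D24 2.11 against 0.96. ZNF395 read 10.56 in LM1 against 8.30 to 8.71 on the other arrays with the probe set used, and stood -0.06 and -0.01 from the midpoint on others. GTF2I, ZNF675, SOD2 and COXFA4L3 were each read by a single probe set, so no such check was possible.

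Of the 34 lists 0 passed camera (lowest adjusted p = 0.261; 5 at an unadjusted p under 0.05) and 0 passed fry, with 4 passing camera on the mean of all probe sets. Adjusted over the list alone, HSP90B1 (2.48), NFKB2 (2.58), NRP1 (1.25), MYC (1.10) and DUSP1 (0.60) were higher in LM2 than on the LM1 array. CDH2 (-0.92), KLF10 (-1.31), PDK1 (-1.11), PFKFB3 (-0.76), NDRG1 (-0.85), DNAJC3 (-1.39), CALR (-0.76), KLF6 (-0.95), PMEPA1 (-1.17), TP53INP1 (-1.21), ELOVL6 (-1.28) and SOD2 (-2.10) were lower. These calls hold no spread of LM1 itself. Across 7195 genes with several probe sets, LM2 minus LM1 correlated between the 2 brightest at r = 0.035, against 0.671 for LM2 minus SN12C. The difference of the single arrays SN12C replicate 1 and replicate 2 gave r = 0.455. LM1 was also set against the midpoint of SN12C and LM2: limma called 0 genes (lowest adjusted p = 0.113; 3094 at an unadjusted p under 0.05), and 683 genes departed by at least 1 log2 unit, 454 higher and 229 lower. Without SN12C replicate 1 or 2 it called 2254 or 3719, with the spread of the LM2 pair alone.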

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

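Of the tests here, those on SN12C replicate 2 were chosen after the result was seen, and a second test of mixed RNA was added after the first gave no decision. Those on the LM1 array were written before their results were seen.

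Control probe sets outside the comparisons showed a 3' signal on the LM1 array above that on the other 4: beta-actin was 3.43 log2 units higher at the 3' end than at the 5' end, against at most 0.47, and GAPDH 2.09, against at most 0.14.

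LM1 departed from the midpoint of SN12C and LM2 by at least 1 log2 unit for 683 genes, EIF5A and RAP2B among them. After quantile normalization 92.5% as many genes departed. This does not decide on scaling of the array, because RMA already quantile normalizes and a second pass could change little. Degraded RNA may account for much of the pattern: between the 2 brightest probe sets of a gene, the LM1 departure correlated at r = 0.065 across genes, against 0.671 for LM2 minus SN12C. That reference averages 2 arrays per line, while LM1 has 1. The difference of the single arrays SN12C replicate 1 and replicate 2 gave r = 0.455. Expression particular to the LM1 line stays open, because the number of LM1 arrays is 1, and LM1 line and LM1 array cannot be told apart.

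SN12C replicate 2 lay nearer to LM2 than to SN12C replicate 1. It had 8946 and 9187 probe sets with values identical to those of LM2 replicates 1 and 2, against 5170 for SN12C replicate 1. The LM2 replicates shared 10104. How such ties arose is not given in the sources used here. A mislabelled LM2 sample is argued against: over 29 genes at least 3 log2 units apart between replicate 1 and LM2, replicate 2 lay 37.5% of the way to LM2 in the median. For LM2 RNA mixed into replicate 2, the first test gave an implied share of 6.5%, between its 2 bounds and so undecided. The second test argues against a mixture as the whole cause: genes lower in LM2 implied a share of 69.2%, outside the quartiles of 4.7% to 17.1% from genes higher in LM2, though a small share beside another difference is not excluded. An inflammatory state of the replicate 1 culture is a candidate explanation. The NF-kappaB list without chemokines lay at percentile 100 of matched random lists for replicate 1 minus replicate 2, with a median of 0.52. This was found and tested on the same arrays. The percentile does not single out inflammation: it was 100 for the integrated stress response, 99.9 for the EGFR list and 99.4 for YAP/TEAD targets, whose median was 0. Other lists ranged down to 0 for DNA replication. A technical difference of the replicate 1 array stays open beside it. Its middle and 5' probe sets of 18S ribosomal RNA read 8.68 and 8.80, against 7.43 to 7.83 on SN12C replicate 2 and LM2. The 3' probe set was closer, at 8.49 against 7.98 to 8.22. The SD of all values on that array was 2.11, against 2.22 to 2.25 on the other arrays. Whether a technical difference reaches the genes above was not tested.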

How the results depend on the processing

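The tests of genes with tied values left out, of lists without _x_at and _s_at probe sets and of the overlap without each replicate or without shared arrays were chosen after the data were seen. Leaving out each replicate gave 0 to 3835 genes for LM2 against SN12C, 0 to 4862 for LM1 against SN12C, 0 to 1436 for LM2 against LM1, 0 to 3719 for the LM1 midpoint and 0 to 3084 shared genes. All counts above 0 came without an SN12C array, where SN12C and LM1 have 1 array each and the spread is that of the LM2 pair alone (median gap 0.07, against 0.28 for the SN12C pair), so they do not show how SN12C varies. Without replicate 1 they were 0, 2032, 1425, 2254 and 0. The LM2 and LM1 arrays alone, with the same source of spread, gave 1297 genes. Without genes with tied values LM2 against SN12C had 2, COL11A1 and CXCL5 (limma adjusted p = 0.0255 each), named after their values were seen. Lists for LM2 against SN12C numbered 6 to 10 with a replicate left out, 4 without _x_at and _s_at probe sets, 0 with an estimated correlation and 3 by fry. For LM1 against SN12C they numbered 1, 0 and 0 under the last 3 settings, and for LM2 against LM1 4 with the mean of all probe sets. Chromosomes numbered 3 to 9 with a replicate left out and 0 with an estimated correlation. The integrated stress response turned in camera without SN12C replicate 1, where its median was -0.08 (adjusted p = 0.951), medians running from -0.83 to -0.08 with a replicate left out (adjusted p over its alternatives 1.4e-06 to 0.951). The cause was not tested.

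None of the largest-difference genes passed in the main fit. Of their 485 values under alternatives, 447 still did not pass, 38 passed and 0 reversed. The absence of reversals says little, because these genes were chosen for large differences on the same arrays. Of 242 values of called lists, 189 stayed, 52 were no longer past it and 1 reversed. Deviations of SN12C and LM2 replicates of 1 number correlated at 0.092 across genes. With 2 pairs this can neither show nor exclude a batch shared by replicates of 1 number. A fit with a replicate block called 0 genes, 10 lists and 8 chromosomes. Signal over background limits genes near the filter value of 6.03.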

Other observations

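The tests on chromosomes were chosen after the result was seen; the test on MIF was written before its result was seen.

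Genes of the integrated stress response and DNA replication separated the SN12C replicates more than they separated SN12C replicate 2 from LM2. TRIB3 stood at 11.25 and 9.18 in the SN12C arrays and at 8.93 and 9.11 in LM2. MCM10 stood at 8.92 and 11.06 in SN12C and at 10.91 and 10.95 in LM2. CXCL5 did not follow this, at 11.21 and 11.48 in SN12C and 7.24 and 7.51 in LM2, and neither did MIF, at 13.17 and 13.48 against 6.44 and 7.97.

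Whole chromosomes, led by 2, 4, 14 and 21, shifted between SN12C and LM2. Chance placement of changed genes is argued against: the SD of the medians of 152 runs of neighbouring genes was 0.104, above all 1000 shuffles of the genes (highest 0.036). A single SN12C array as the source is argued against too, since run medians of LM2 minus SN12C from replicate 1 and from replicate 2, which share no array, correlated at 0.789 (highest shuffle 0.481). Run medians of LM1 minus SN12C replicate 1 and LM2 minus replicate 2 correlated at 0.652 (highest shuffle 0.42). The SN12C replicates themselves also differed slightly by position, with an SD of 0.068 against at most 0.065 in shuffles. Copy number differences between the lines may account for the shifts and stay open, with 0 DNA measurements used here.

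For the low MIF signal in LM1 and LM2, loss of the chromosome segment that holds MIF was tested as a hypothesis. The 10 measured neighbours, among them SMARCB1 and CABIN1, had a median LM2 minus SN12C difference of 0.07, and 0 of 10 were lower by at least 1 log2 unit, which argues against a loss reaching these genes. A loss of MIF alone was not tested.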
